A study of Homo sapiens with 3 samples.

How the data were processed

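Droplet libraries of BxPC-3 cells were made with the 10x Chromium 5' kit of version 2, per the labels' protocols. Each of 3 groups, parental, single-positive and double-positive, had 1 library. Per the labels the groups were set by sorting on EGFP and mCherry, and no feature for either protein was used here, so the gate itself could not be checked in the RNA. The labels do not say whether the single-positive library pooled both colours, nor when the cells were expanded.

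The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode. Per the file headers they were written by Cell Ranger, and the submitters' processing notes list Cell Ranger 4.0.0, Seurat 4.0.6 and build GRCh38. The annotation release is not given in the sources used here. The matrices were not filtered for cells: each lists 737280 barcodes and 33694 features. Positions were taken from GENCODE 29 on GRCh38 by gene identifier, which matched 33132 features.

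Cells were called as barcodes with at least the 99th percentile of UMIs over the top 3000 barcodes divided by 10, at least 500 genes and at most 20% mitochondrial UMIs. This kept 2412 parental, 1248 single-positive and 1942 double-positive cells, holding 98.0%, 97.0% and 97.8% of all UMIs. No called barcode was over the mitochondrial limit. No droplet was removed as a doublet, since the double-positive gate selects on both signals and a cell inside another cell could be marked as one. Scrublet marked 0.207%, 0.160% and 0.412% of cells, too few to tell whether it worked.

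UMIs were summed over the cells of a library and scaled to counts per 1000000 UMIs (CPM). Log2 ratios of CPM were given with exact conditional binomial (Clopper-Pearson) intervals at 95%. Cells within a library are not replicates, so no p-value was computed. Genes with a mean of at least 10 CPM over the 3 libraries were counted where they lay at least 2-fold apart, as a description of size. There were 34 gene lists, chosen for entosis, cell cycle, stress, metabolism, cytoskeleton and carcinoma subtypes. Members with a mean of at least 5 CPM entered, and the list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A median below percentile 2.5 or above 97.5 was treated as standing apart. Genes of a list are regulated together, so the percentile describes these libraries and is not a test.

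Genes were named by a rule. It took the 8 highest and 8 lowest CPM ratios among genes with at least 30 CPM in the higher library, without mitochondrial, ribosomal protein, clone-named, antisense and Y-linked genes, then up to 3 members of each list described, and 12 genes of adhesion, contractility and cell cycle in every comparison. The lists, thresholds, rule and most alternatives were fixed before the data were examined. Phases were scored on cells thinned to 3000 UMIs, and no cell was below that depth. All 5602 cells were clustered together with Leiden on 2000 variable genes and 30 principal components at resolution 0.5, which gave 8 clusters. Clusters were used for weighting and to look for other cell types, and their sizes were not compared between groups. In cluster 5, 182 of 199 droplets came from the single-positive library, where their median was 11418 UMIs, and this cluster was left out in an alternative.

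Alternatives changed the cell call, the mitochondrial limit, scaling, weighting of cells, depth, doublets, ambient RNA, cell size, phase and expression floor. A further 3 were added after seeing the data: without cluster 5, without droplets under 0.5% mitochondrial UMIs, and with clusters weighted the same in every library. Ambient RNA was taken from barcodes with 100 UMIs or fewer, and 10% of each library's UMIs in cells was subtracted in proportion to it. The shared UMI range ran from 25023 to 32953 UMIs per cell, the highest lower quartile and the lowest upper quartile of the libraries. For the test of cell pairs, the 200 genes most variable in parental cells at 100 CPM or more were compared with sums of randomly drawn cells, without cluster 5.

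The steps were tested on simulated data drawn from the real means of 7701 genes. For double-positive against single-positive cells, 100% of genes set 2.5-fold or 4-fold higher or to 0.25-fold passed 2-fold, 0% of unchanged and of 1.5-fold genes did, and the intervals covered the true ratio for 95.6% of genes. Of 200 unchanged lists, 5% fell outside the central 95% of random lists. These counts were drawn independently from a shared profile, without spread between libraries or genes regulated together. The simulation therefore checks the computation and does not show how the intervals or lists behave under such variation. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.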

Results

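Single-cell transcriptomes were compared between 3 populations of BxPC-3, an established line of human pancreatic ductal adenocarcinoma cells. Cells carrying EGFP and cells carrying mCherry were mixed and kept in suspension, a condition in which adherent epithelial cells can enter one another to form cell-in-cell structures (entosis). Cells with both fluorescent signals were sorted as double-positive and cells with a single signal as single-positive, and parental cells served as the reference. Each population was represented by 1 library, so no difference below has a replicate check, and no test between conditions was possible. The protocol in the labels speaks of expanded cells, and does not say whether the expansion came before or after sorting.

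The parental library held 65107147 unique molecular identifiers (UMIs), the single-positive library 51637677 and the double-positive library 62517276. Cell calling kept 2412 parental, 1248 single-positive and 1942 double-positive cells, with medians of 23280, 38922 and 29953 UMIs per cell and 4784.5, 5957.5 and 5371 genes per cell. After each cell was thinned to 3000 UMIs, the median number of genes was 1429, 1457 and 1435, so most of the gap in detected genes went with depth. All intervals are 95% intervals from the counts, and they cover counting error only. Over 13 alternatives in cells, weighting and scaling, absolute log2 ratios were compared with the main ones, without regard to sign. They changed by over 1.5 times in at least 1 for 53 of 69 named genes in double-positive against single-positive cells. The counts were 63 of 77 in single-positive against parental and 67 of 84 in double-positive against parental cells. The same held for the medians of 13 of 15, 19 of 20 and 21 of 21 lists that stood apart. Small ratios count as changed after slight shifts, and the values below hold for the main processing unless a setting is named. Over all 7683 genes counted, the median log2 ratio was -0.022, 0.048 and 0.026 in these comparisons. With median-of-ratios scaling it was 0.018, -0.016 and 0.002, so small values can turn sign from this shift alone. Counts of list members higher or lower include the shift, and the matched random lists carry it too.

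All 3 libraries had the profile of an epithelial carcinoma line. Summed over 9 epithelial markers such as KRT7, KRT19 and EPCAM, expression was 8988 counts per 1000000 UMIs (CPM) in parental, 9058 CPM in single-positive and 8230 CPM in double-positive cells. Fibroblast markers together reached 3.28, 2.63 and 3.06 CPM, and endothelial markers 0.470, 0.379 and 0.278 CPM. Immune markers summed to 44.5, 32.9 and 36.7 CPM, of which CD68, a lysosomal protein that is not restricted to immune cells, gave 39.1, 29.2 and 32.0 CPM. Erythroid markers stayed at 0.329, 0.240 and 0.278 CPM, and neural or endocrine markers at 0.345, 0.499 and 0.425 CPM.

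The share of cells called G1 was 51.7% in parental (exact Clopper-Pearson interval 49.7 to 53.8%), 40.5% in single-positive (37.8 to 43.3%) and 43.6% in double-positive cells (41.4 to 45.9%) after thinning. Without thinning the shares were 46.5%, 34.5% and 43.7%. G2M calls made up 35.8%, 44.1% and 39.7% of thinned cells, and S calls 12.5%, 15.4% and 16.7%. Without cluster 5, single-positive cells had 40.1% G2M and 17.6% S calls, against 39.5% and 16.7% in double-positive cells, so the G2M gap between them nearly closed and the order of S calls turned. Free RNA in the droplets can enter these scores, and its share differed between libraries. It was small, though: the 10000 largest uncalled double-positive barcodes held a mean of 65.2 UMIs, beside a median of 29953 UMIs per cell. The calls also moved with thinning and without cluster 5, so alone they do not measure proliferation.

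Double-positive and single-positive cells went through the same mixing and sorting, and this comparison asks what distinguishes cells with both signals. The clearest difference was in transcripts of the mitochondrial genome, which encode subunits of the respiratory chain and ATP synthase. All 13 measured members of that list were higher in double-positive cells, with a median log2 ratio of 0.75, above 100% of 10000 random lists matched on expression, and 11 of them were at least 1.5-fold higher. MT-CO2 was at 7543 CPM against 4176 CPM (log2 ratio 0.85, interval 0.85 to 0.86), MT-ATP8 had a log2 ratio of 0.95 and MT-ND4L of 0.82. Nuclear-encoded subunits of the same complexes did not stand apart, with a median of -0.04 over 40 genes (percentile 4.6).

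**Figure D1:**
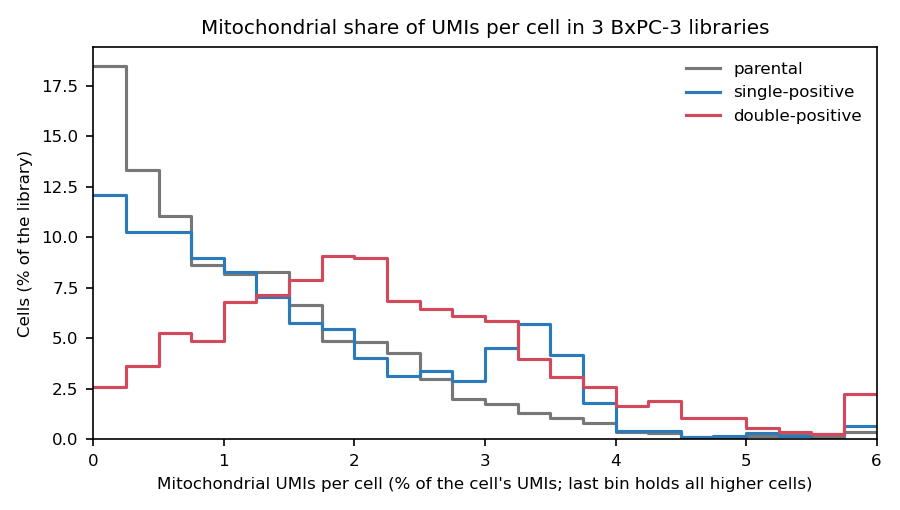
Mitochondrial UMIs as a percentage of each cell's UMIs (x axis, the last bin holding all higher cells) against the percentage of cells in the library (y axis), with 1 line for each library. The medians per cell are 0.948% in parental, 1.254% in single-positive and 2.08% in double-positive cells, and cells under 0.5% make up 31.8%, 22.4% and 6.18% of the libraries.

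DHRS2, a short-chain dehydrogenase of mitochondria and nucleus (ENSG00000100867, GRCh38 chromosome 14, 23630115 to 23645639), was the single nuclear gene at least 2-fold higher in double-positive cells among 7683 genes with a mean of at least 10 CPM. It stood at 467 CPM against 198 CPM, a log2 ratio of 1.24 (1.203 to 1.269), but at 0.84 among G1 cells it was not 2-fold higher and S100A8 was the only gene that was. KRT23, a type I keratin, followed with 0.91 (0.84 to 0.97). ADGRF1, an adhesion G protein-coupled receptor, had 0.75, SYT8 0.66, FAM46A 0.60, PLAT, which encodes tissue plasminogen activator, 0.58 (0.24 among G1 cells), GALNT5 0.51 (0.32 to 0.92 over the alternatives) and SPRR2A, a cornified envelope gene whose reads can be shared with SPRR2D, 0.51 (0.23 to 1.90).

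On the other side, 7 genes were at least 2-fold lower. LY6D, a GPI-anchored surface protein of stratified epithelium (ENSG00000167656, chromosome 8, 142784880 to 142786592), was at 28.2 CPM against 64.7 CPM (log2 ratio -1.20, interval -1.28 to -1.11). VIM, which encodes the mesenchymal intermediate filament vimentin (ENSG00000026025, chromosome 10, 17228259 to 17237593), was at 35.0 CPM against 77.6 CPM (-1.15), and KRT4, a keratin of mucosal epithelium, at 22.8 CPM against 50.3 CPM (-1.14). The remaining 4, CALB1 (-1.87), GAL (-1.65), LYNX1 (-1.05) and DEFB1 (-1.04), lay below the 30 CPM of the naming rule and were named after their values were seen; over the 13 alternatives GAL was 2-fold lower in 13, CALB1, KRT4 and LY6D in 12, VIM in 11, LYNX1 in 10 and DEFB1 in 9. TFF1, a secreted trefoil peptide, had -0.95, KLK11 -0.79, UPK3B -0.79, and the histone genes HIST1H2AJ and HIST1H2AI -0.92 and -0.78 (-0.13 and -0.03 in the shared UMI range). Of all genes counted, 18 were at least 1.5-fold higher and 24 lower.

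**Figure D2:**
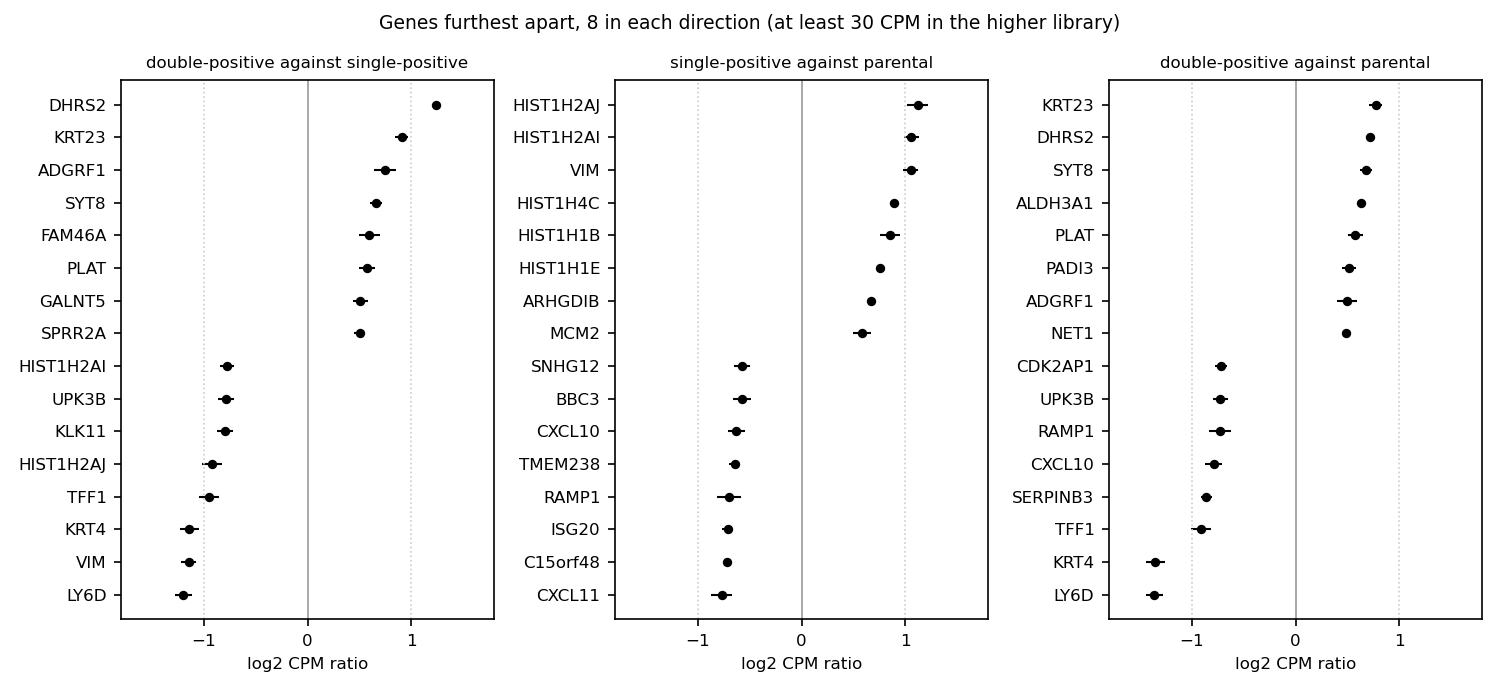
Log2 CPM ratios (x axis) of the 8 highest and 8 lowest genes by the naming rule (y axis) in each of the 3 comparisons, with bars for the 95% counting interval and dotted lines at 2-fold. DHRS2 is at 1.24 and LY6D at -1.20 in double-positive against single-positive cells, and HIST1H2AJ is at 1.12 in single-positive against parental cells.

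Of the 34 gene lists, 15 stood apart from matched random lists in this comparison. The single-positive library also enters the next comparison, so a departure of that library appears in both with opposite sign. Against parental cells, double-positive medians were -0.07 for interferon genes, -0.05 for p53 targets, 0.19 for S phase genes and 0.02 for tubulins. They were 0.03 for actin and myosin genes, 0.01 for metallothioneins and -0.01 for squamous genes, lists that did not stand apart there. Cholesterol synthesis (-0.12), NRF2 targets (-0.09) and the mitochondrial list (1.15) kept their direction there. So did glycolysis (-0.05), fatty acid (-0.05), immediate early (-0.06) and classical subtype genes (-0.25). Interferon response genes were higher, with 26 of 37 members above the single-positive level and a median of 0.11. IFI6 had 0.40, and ISG20, an antiviral exonuclease, 0.40. Targets of p53 were higher in 16 of 21 members (median 0.13, but 0.05 in thinned cells and 0.34 in the shared UMI range), among them SESN1 (0.29, and 0.03 among G1 cells), SESN2 (0.28, turning to -0.21 in the shared UMI range) and BTG2 (0.25), and CDKN1A, the cell cycle inhibitor p21, had 0.21. Squamous differentiation genes had a median of 0.08, with S100A8 at 1.16 and KRT4 at -1.14. S100A8 lay below the mean of 10 CPM set for counting, and ranged from 1.09 to 5.96 over the alternatives.

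Lists of lipid and sugar metabolism were lower in double-positive cells. Cholesterol synthesis genes had a median of -0.18 (17 of 25 lower), with MVK at -0.39 and ACAT2 at -0.38, and fatty acid and lipid droplet genes a median of -0.15 (16 of 19 lower), with DGAT2 at -0.72 and SCD at -0.35. Glycolysis genes had -0.14 (12 of 16 lower; -0.06 in the shared UMI range), among them the lactate transporter SLC16A3 at -0.32. NRF2 target genes had -0.12 (21 of 26 lower; -0.23 in that range), led by the sulfiredoxin gene SRXN1 at -0.61, and metallothioneins -0.27 (4 of 5 lower), with MT1E at -0.40.

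Cytoskeletal lists were also lower. All 8 tubulins were lower (median -0.18), with TUBB at -0.33 (0.17 in the shared UMI range), and 21 of 31 actin and myosin genes (median -0.10), with TPM2 at -0.65 and TPM1 at -0.35. Epithelial-mesenchymal transition genes had a median of -0.12, where VIM was followed by S100A4 (-0.56) and MMP1 (-0.44). Against parental cells the median of this list was 0.093 in single-positive and 0.085 in double-positive cells, and it stood apart in neither. S phase genes had a median of -0.16 (34 of 41 lower), immediate early and heat shock genes -0.08, with HSPH1 at -0.47, and the 6 measured classical subtype genes -0.20 (-0.33 among G1 cells and -0.08 with clusters weighted alike), with TFF1, at -0.40 in the shared UMI range, and TFF2 (-0.87) lower and PLA2G10 at 0.54.

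The list of entosis and cell-in-cell machinery did not stand apart, with a median of -0.03 that turned to 0.01 with median-of-ratios scaling. E-cadherin (CDH1) had 0.20 (0.13 to 0.26), and NET1, a RhoA exchange factor, 0.31 (0.27 to 0.36). RHOA had 0.02, ROCK1 0.01 (-0.05 to 0.36 over the alternatives), CTNNA1 -0.09, MYL9 -0.47 and moesin (MSN) -0.43, while ezrin (EZR) at -0.01, ROCK2 at -0.03 and CD44 at -0.03 turned sign with that scaling. Lysosome genes had a median of -0.01, which turned to 0.03 with the same scaling and differed in sign from their mean of 0.01, and autophagy genes a median of 0.02.

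Without droplets under 0.5% mitochondrial UMIs the median of the mitochondrial list was 0.41 in place of 0.75, though that filter acts on the compared share itself, 0.41 in the shared UMI range and 0.47 with the mean of per-cell CPM, and in thinned cells the metallothionein median was -0.008. Among cells of a shared UMI range, which left 117 single-positive cells, the medians of S phase genes (0.46), tubulins (0.17) and squamous genes (-0.06) had the opposite sign, and that of epithelial-mesenchymal transition genes was -0.01. Phases were not matched in that range, where 20.5% of single-positive and 36.7% of double-positive cells were called G2M.

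Single-positive against parental cells asks how cells of the mixed culture that carried a single signal differed from the parental line. Replication-dependent histone genes and VIM were highest: HIST1H2AJ had a log2 ratio of 1.12 (1.02 to 1.22), HIST1H2AI 1.06 and VIM 1.05 (0.98 to 1.13), each at least 2-fold. They were 2-fold higher in 9, 8 and 6 of the 13 alternatives, and none was in the shared UMI range. HIST1H4C (0.89), HIST1H1B (0.85), HIST1H1E (0.76), ARHGDIB (0.67) and MCM2, a subunit of the replicative helicase (0.58), completed the highest 8. Most histone transcripts of this kind lack a poly(A) tail and have near-identical copies, so their capture and assignment are uncertain. Of the 7 genes at least 2-fold higher, HIST1H2AH (1.33), CALB1 (1.27), HIST2H2AC (1.24) and HIST1H3C (1.10) were below the level of the naming rule and were named after their values were seen.

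Among the lowest genes, the chemokine CXCL11 had -0.77, C15orf48, a mitochondrial cytochrome c oxidase-associated protein, -0.72, ISG20 -0.71, RAMP1 -0.70, TMEM238 -0.65, CXCL10 -0.63, the p53 target BBC3 -0.57 and SNHG12 -0.57. The genes at least 2-fold lower were PRSS1, encoding cationic trypsinogen, at -2.44 (-2.65 to -2.23) and the xenobiotic-metabolising cytochrome CYP1A1 at -1.002, both named after their values were seen. PRSS1 shares sequence with PRSS2, so reads can be divided between them. PRSS1 was 2-fold lower in 11 and CYP1A1 in 6 of the 13 alternatives. At least 1.5-fold apart were 17 higher and 13 lower genes.

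Here 20 lists stood apart, beside a median of 0.048 over all 7683 genes counted. S phase genes were higher in 39 of 41 members (median 0.34), with MCM2 at 0.58, MCM5 at 0.51 and HELLS at 0.51, and G2M genes in 42 of 51 (median 0.18), with NCAPD2 at 0.50 and MKI67 at 0.42. DNA damage genes were higher in 20 of 21 members (median 0.25), among them FANCI (0.36) and PARP1 (0.31), and tubulins in 7 of 8 (median 0.19). Mitochondrially encoded transcripts were higher in all 13 members (median 0.39), with MT-ND6 at 0.69. That median was 0.12 with 10% of UMIs subtracted as ambient RNA, far more per cell than a near-empty droplet held (100 UMIs or fewer). It was 0.16 without droplets under 0.5% mitochondrial UMIs and 0.26 without cluster 5, 182 of whose 199 droplets were single-positive. Without that cluster MT-ND6 had 0.36. Entosis machinery genes had a median of 0.13 (23 of 31 higher; 0.06 without droplets under 0.5% mitochondrial UMIs), with MSN at 0.45, ROCK2 at 0.33 (0.19 to 0.48) and EZR at 0.21, while CDH1 at 0.04 turned to -0.02 with median-of-ratios scaling.

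Adhesion and cytoskeleton lists were higher too: integrins and basement membrane genes had a median of 0.14 (17 of 18 higher), with LAMB1 at 0.51, YAP and TAZ targets 0.15 (17 of 19 higher), with AXL at 0.48, actin and myosin genes 0.10, with FLNA at 0.34, and endocytosis genes 0.11. Fatty acid genes had a median of 0.15 (17 of 19 higher). Nuclear-retained RNAs had 0.28 over 4 members, 0.16 without cluster 5 and 0.09 in the shared UMI range, where MALAT1 turned from 0.24 to -0.055.

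Interferon response genes were lower in 33 of 37 members (median -0.17), p53 targets in 15 of 21 (-0.16), with SESN2 at -0.49 and CDKN1A at -0.27, and NF-kB and cytokine genes in 18 of 26 (-0.12), with BIRC3 at -0.60 and CSF2 at -0.49. Amino acid response genes had a median of -0.06, with TRIB3 at -0.46 (0.25 in the shared UMI range). S100 and annexin genes had -0.09, with S100A8, below the 10 CPM set for counting, at -1.23 (-5.93 to -0.90 over the alternatives). Lysosome genes had -0.04, basal-like subtype genes -0.11, with SPRR3 at -0.45 and TNS4 at 0.50, and squamous genes -0.07.

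**Figure D3:**
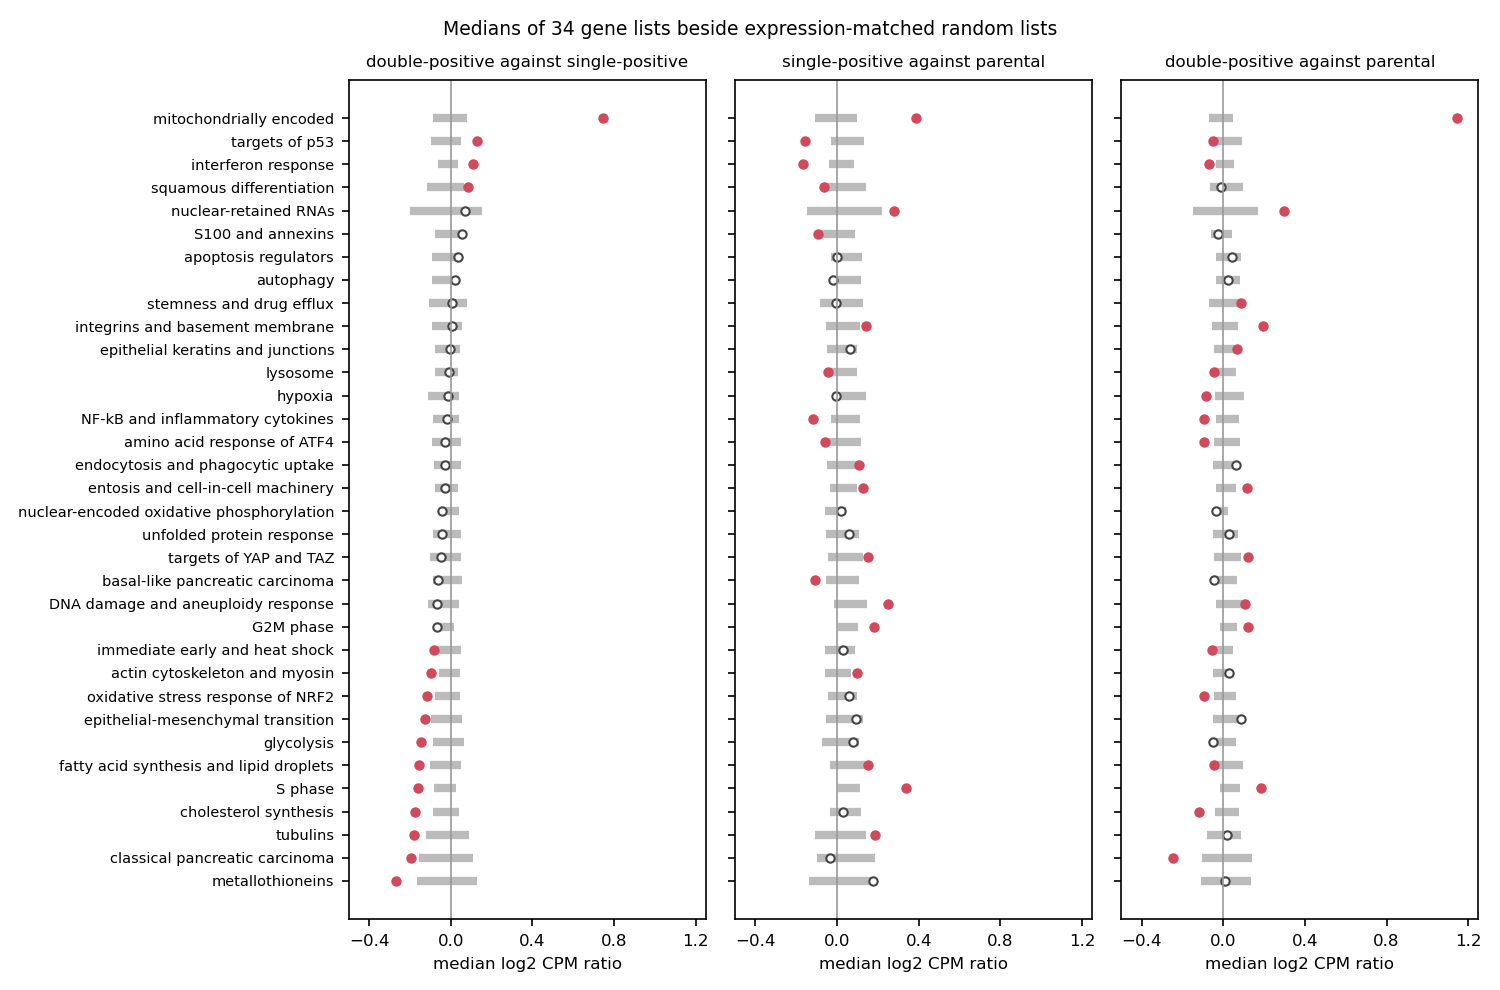
Median log2 CPM ratio (x axis) of each of the 34 gene lists (y axis) in the 3 comparisons, with grey bars for the central 95% of matched random lists and filled points for medians outside it. The mitochondrially encoded list is at 0.75, 0.39 and 1.15, and the interferon response list at 0.11, -0.17 and -0.07.

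In the shared UMI range the medians of S phase (-0.31), G2M (-1.17), tubulin (-0.42) and DNA damage genes (-0.30) were below 0, and so were MKI67 (-1.03), NCAPD2 (-0.50), HELLS (-0.24), FANCI (-0.77), HIST1H2AI (-0.07), HIST1H1B (-0.72) and HIST1H1E (-0.06), whereas VIM stayed at 0.87. Of the 117 single-positive cells in that range 20.5% were called G2M, against 49.8% of 434 parental cells, so phases were not matched there. With 10% of UMIs subtracted as ambient RNA CXCL10 turned to 0.44. With clusters weighted alike CALB1 and HIST1H2AH were the only genes 2-fold higher. There the medians of NF-kB (0.02), basal-like (0.02), squamous (0.12) and G2M genes (-0.03) turned sign.

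Double-positive cells against parental cells set the sorted cells beside the starting population. All 12 genes at least 2-fold higher were mitochondrially encoded, and the list of 13 had a median log2 ratio of 1.15, with MT-ND4L at 1.23, MT-ND1 at 1.21 and MT-CO3 at 1.19. KRT23 had 0.77 (0.71 to 0.83), DHRS2 0.72 (0.69 to 0.74), SYT8 0.68, ALDH3A1, an aldehyde dehydrogenase, 0.64, PLAT 0.58, PADI3 0.52, ADGRF1 0.50 and NET1 0.49 (0.45 to 0.53). VIM was near the parental level, at 35.0 CPM against 37.3 CPM (-0.09, turning to 0.13 in the shared UMI range).

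The lowest genes by the naming rule were LY6D at -1.36 (-1.44 to -1.28) and KRT4 at -1.35 (-1.44 to -1.26). TFF1 had -0.91, SERPINB3, which shares reads with SERPINB4, -0.86, CXCL10 -0.79, RAMP1 -0.73, UPK3B -0.73 and CDK2AP1 -0.72. PRSS1 (-2.53), LYNX1 (-1.86) and GAL (-1.36) were also at least 2-fold lower and were named after their values were seen, and with clusters weighted alike GAL was the only gene 2-fold lower. KRT4, LYNX1, PRSS1 and TFF1 were among the 10 leading genes of cluster 2. At least 1.5-fold apart were 18 higher and 22 lower genes.

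Of the lists, 21 stood apart. Integrins and basement membrane genes had a median of 0.20 (16 of 18 higher), with ITGA6 at 0.26, entosis machinery genes 0.12 (24 of 31 higher), with NET1 followed by CDH3 (0.38) and CDH1 (0.24), YAP and TAZ targets 0.12, and stemness and drug efflux genes 0.09, with MET at 0.29. Epithelial keratin and junction genes had a median of 0.07 and a mean of -0.01, opposite in sign, with KRT5 at 0.25 and KRT14, below the 10 CPM set for counting, at -1.70. S phase genes had 0.19, G2M genes 0.12, DNA damage genes 0.11 and nuclear-retained RNAs 0.30.

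Classical subtype genes were lower in 5 of 6 members (median -0.25), with AGR2 at -0.51. Cholesterol synthesis genes were lower in 20 of 25 (-0.12), with MSMO1 at -0.38, NRF2 targets in 20 of 26 (-0.09), with HMOX1 at -0.85 (-0.08 in the shared UMI range) and the ferritin genes FTH1 and FTL at -0.44 and -0.27, and amino acid response genes in 17 of 20 (-0.09), with NUPR1 at -0.86. NF-kB genes had -0.09, with LCN2 at -0.42, interferon genes -0.07, hypoxia genes -0.08, with DDIT4 at -0.39 (0.08 among G1 cells), immediate early genes -0.06, with ATF3 at -0.36, p53 targets -0.05, fatty acid genes -0.05 and lysosome genes -0.04.

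Without droplets under 0.5% mitochondrial UMIs the mitochondrial median was 0.58 with none of these genes 2-fold higher, and the medians of entosis (0.02), YAP and TAZ (0.03), nuclear-retained (0.04), keratin (0.02), S phase (0.06), G2M (0.05), DNA damage (0.03) and integrin genes (0.10) came closer to 0. Among G1 cells the medians of S phase (-0.18), G2M (-0.23), hypoxia (0.04) and DNA damage genes (-0.04) turned sign, and with clusters weighted alike so did classical genes (0.03) and LCN2 (0.29), while LY6D (-0.41), KRT4 (-0.33), TFF1 (-0.06), SERPINB3 (-0.25), RAMP1 (-0.24) and UPK3B (-0.29) came closer to 0.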

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

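All tests on mitochondrial transcripts, VIM and histones below were chosen after the result was seen.

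Near-empty droplets held a larger mitochondrial share of UMIs in the single-positive and double-positive libraries than in the parental library. In near-empty droplets, 4.93% of UMIs were mitochondrial in the single-positive and 4.87% in the double-positive library, above 2.97% in the parental library. Near-empty droplets took 1.66% of UMIs in the single-positive and 1.40% in the double-positive library against 1.14% in the parental library. Of barcodes with 500 UMIs or more, 93 of 1429 (6.51%, 5.29 to 7.91%) were over the mitochondrial limit in the single-positive library. The counts were 109 of 2630 (4.14%, 3.42 to 4.98%) in the parental and 121 of 2129 (5.68%) in the double-positive library. These totals include the 1248, 2412 and 1942 called cells, none of them over the limit. The shares therefore depend on how many cells were called and do not describe uncalled droplets alone.

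Mitochondrially encoded transcripts were higher in double-positive than in single-positive cells, with a median log2 ratio of 0.75, and the median share per cell was above the single-positive one in 7 of 8 clusters. Leaving out droplets under 0.5% mitochondrial UMIs left a median of 0.41, which argues against a smaller share of such droplets as the whole cause. That filter acts on the compared share itself and can lower the ratio under any cause, so the fall from 0.75 does not show what part these droplets had, and droplets just above that limit stay open. Free RNA would have to make up 23.4% of UMIs, and the 10000 largest uncalled barcodes held a mean of 65.2 UMIs, 0.009 of the amount needed in a cell of median UMIs, which argues against free RNA. The 4 measured nuclear-retained RNAs, which a leaking cell would keep, reached 0.205 of the mitochondrial log2 ratio without cluster 5. Their median ranged from -0.196 to 0.183 over the 13 alternatives and was highest without cluster 5. As far as 4 RNAs can show, this argues against leakage as the whole cause. The median was also 0.41 in the shared UMI range and 0.47 with the mean of per-cell CPM, so UMIs per cell as part of the cause, a state of the cells that goes with the double signal, the sort and later growth all stay open, since each group has 1 library and no biological explanation was tested.

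VIM and the histone genes HIST1H2AJ, HIST1H2AI, HIST1H4C and HIST1H1B were higher in single-positive than in parental cells, with a median of 1.05 over the 5 genes. The median was 0.97 without cluster 5, which argues against its low-UMI droplets as the whole cause. Among G1 cells the median was 0.79, but the G1 calls did not even out S phase transcripts. MCM5 had 0.62 there against 0.51 in all cells. S phase genes in double-positive against single-positive cells had a median of -0.40 among G1 cells against -0.16 in all cells. The G1 values therefore cannot decide on phase, which stays open as a cause. Among cells of the shared UMI range VIM kept 0.87, which argues against UMIs per cell as the whole cause for VIM. UMIs per cell stay open as part of the cause, and VIM was among the 10 leading genes of cluster 3 beside the cycling marker CCNB1. The median of the 4 histones was -0.024 in the shared UMI range. That range held 117 single-positive cells, of which 20.5% were called G2M against 49.8% of parental cells, so for the histones UMIs per cell stay open as a cause, while among G1 cells they kept 0.98, 1.06, 0.59 and 0.73. In 4 equal groups of each library from few to many UMIs, VIM had 0.60, 0.73, 0.83 and 1.55 and the histone median 0.855, 0.68, 0.92 and 1.252; no biological explanation was tested.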

How the results depend on the processing

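The settings without cluster 5, without droplets under 0.5% mitochondrial UMIs and with clusters weighted alike were chosen after seeing the data. No paired analysis was possible because each group had 1 library and the groups share only replicate number 1. Over the 13 alternatives in cells, weighting and scaling, lists that stood apart kept their sign in all for 12 of 15 (double-positive against single-positive), 13 of 20 (single-positive against parental) and 13 of 21 (double-positive against parental), and named genes for 55 of 69, 57 of 77 and 66 of 84. Of list medians, 987 values stayed within their counting interval, 416 moved and 25 reversed, where only lists that stood apart could count as reversed. Removing the mitochondrial limit removed no droplet and tests nothing, and its 102 values are among the 987. The median log2 ratio of VIM in single-positive against parental cells and of the mitochondrial list in every comparison kept its sign throughout. The mitochondrial median ranged from 0.41 to 1.12 (double-positive against single-positive), 0.12 to 0.69 (single-positive against parental) and 0.58 to 1.32 (double-positive against parental). Depth limits the genes under 10 CPM, and 1 library per group limits every comparison. Except where fewer or more genes or cells entered by construction, the cause was not tested.

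Counts of genes at least 2-fold apart follow as higher and lower, where they moved by over 1.5 times. In double-positive against single-positive cells the main counts were 1 higher and 7 lower. Higher genes numbered 2 with median-of-ratios scaling, 5 with thinned cells, 11 with ambient RNA subtracted, 46 in the shared UMI range, 2 without cluster 5, 5 without low-mitochondrial droplets, 2 with clusters weighted alike and 17 at a floor of 1 CPM. Lower genes numbered 13 with thinned cells, 3 with clusters weighted alike, 28 at a floor of 1 CPM, 12 among G1 cells and 1 at a floor of 50 CPM. Among G1 cells the count of higher genes stayed at 1, but the gene was S100A8 in place of DHRS2.

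In single-positive against parental cells, with 7 higher and 2 lower, higher genes numbered 4 in the shared UMI range, 3 without low-mitochondrial droplets, 2 with clusters weighted alike, 22 at 1 CPM, 3 among G1 cells and 1 at 50 CPM. Lower genes numbered 4 with thinned cells, 1 with ambient RNA subtracted, 76 in the shared UMI range, 1 without cluster 5, 6 without low-mitochondrial droplets, 19 at 1 CPM, 4 among G1 cells, 0 at 50 CPM and 5 with the mean of per-cell CPM.

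In double-positive against parental cells, with 12 higher and 5 lower, higher genes numbered 5 with thinned cells, 0 without low-mitochondrial droplets, 4 with clusters weighted alike, 26 at 1 CPM and 4 with the mean of per-cell CPM. Lower genes numbered 13 in the shared UMI range, 1 with clusters weighted alike, 35 at 1 CPM, 9 among G1 cells and 1 at 50 CPM. Raising or lowering the floor changes how many genes are counted by construction.

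Values that changed sign follow, without a full list of named genes, and the cause was not tested. In the shared UMI range, double-positive against single-positive, S phase had 0.46, squamous differentiation -0.061, tubulins 0.17, MKI67 0.58, TUBB 0.17 and SESN2 -0.21. There, single-positive against parental, S phase had -0.31, G2M phase -1.17, tubulins -0.42, DNA damage -0.30, HIST1H2AI -0.067, HIST1H1B -0.72, HIST1H1E -0.064, MKI67 -1.03, NCAPD2 -0.50, HELLS -0.24, FANCI -0.77 and TRIB3 0.25, and double-positive against parental, G2M phase had -0.41, epithelial keratins -0.001 and DNA damage -0.016. With thinned cells squamous differentiation had -0.10 (double-positive against single-positive) and lysosome 0.024 (double-positive against parental). With ambient RNA subtracted CXCL10 had 0.44 (single-positive against parental).

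With clusters weighted alike, single-positive against parental, G2M phase had -0.028, NF-kB 0.025, basal-like carcinoma 0.023 and squamous differentiation 0.12, and double-positive against parental, G2M phase had -0.048, p53 targets 0.009 and classical carcinoma 0.031. Among G1 cells G2M phase had -0.16 in single-positive against parental cells, and in double-positive against parental cells S phase had -0.18, G2M phase -0.23, hypoxia 0.042, p53 targets 0.003 and DNA damage -0.039.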

Other observations

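The test of cell pairs was planned before its result was seen; everything on chromosomes was looked for and chosen after seeing the data.

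Lists of 4 processes tied to the fate of engulfed cells or to stress stood apart in no comparison, in the order double-positive against single-positive, single-positive against parental and double-positive against parental. Autophagy genes had medians of 0.02, -0.02 and 0.02, which turned to -0.02 with the mean of per-cell CPM, 0.06 in the shared UMI range and -0.002 with median-of-ratios scaling. Apoptosis regulators had 0.03, 0.001 and 0.04, the first 2 moving to 0.22 and -0.23 in the shared UMI range and the first turning to -0.002 with ambient RNA subtracted, and unfolded protein response genes -0.05, 0.06 and 0.03, the middle value turning to -0.005 with median-of-ratios scaling. Nuclear-encoded oxidative phosphorylation genes had -0.04, 0.02 and -0.04, the first turning to 0.01 with the mean of per-cell CPM and the middle value to -0.05 with median-of-ratios scaling.

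Double-positive droplets were defined by both colours, and a droplet holding the RNA of a pair of independent cells would average their differences. The excess variance of 200 variable genes in double-positive cells was 0.966 of that in single-positive cells (quartiles over genes 0.765 and 1.15). Simulated pairs of single-positive cells gave 0.504 and simulated pairs of parental cells 0.515, while parental cells gave 0.998. This argues against most double-positive droplets holding RNA of 2 independent cells. Inner cells that had been degraded, cells of related state, and growth after sorting were not separated by this test and stay open.

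Genes of chromosome 8 were lower in the double-positive library. Over 276 genes the median log2 ratio to single-positive cells was -0.13, with 234 genes lower, and 0% of 10000 matched random lists lay below it. The other 22 chromosomes had medians from -0.08 to 0.06. Against parental cells chromosome 8 had -0.07 and the other chromosomes -0.02 to 0.06, and in single-positive against parental cells it had 0.06, within the other chromosomes. Over the 13 alternatives the median to single-positive cells lay between -0.15 and -0.09, after removal of the trend with GC content it was -0.14, and it was below that of the other chromosomes in 7 of 8 clusters. For 63 genes between 5 and 10 CPM it was -0.17, but chromosome 22 had nearly the same value there, -0.16. Of the 7 genes at least 2-fold lower in double-positive than in single-positive cells, 4 are on chromosome 8: CALB1, DEFB1, LY6D and LYNX1. With clusters weighted alike only CALB1, GAL and VIM stayed 2-fold lower, and of these only CALB1 is on chromosome 8.

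This pattern came out of several looks along the genome that did not give one answer. Rolling windows of 30 genes at 20 CPM or more were lowest on chromosome 8 (132775358 to 144529132, median -0.25), and a segment near that end was then drawn by hand. A scan of 187 fixed windows put a window of 19 genes on X first (154010500 to 155943769, -0.19) and chromosome 8 next (-0.16), and against parental cells the lowest fixed window was on chromosome 16 (-0.10). Rolling windows of double-positive against parental cells were lowest on chromosome 8 (-0.17), with chromosome 16 next (-0.12). For the window on X the median was -0.15 after removal of the GC trend and -0.19 with clusters weighted alike, while 6 genes between 5 and 20 CPM had -0.001. The fixed window before it on X had -0.10, and the lowest rolling window on X -0.18, next after chromosome 8. At the other end, double-positive against single-positive windows were highest on chromosome 14 (fixed, 0.12) and chromosome 7 (rolling, 0.16). In single-positive against parental cells the lowest rolling (-0.12) and fixed (-0.10) windows were on chromosome 14. Whole chromosomes were taken up last. The choice of chromosome 8 and of this scale followed from the values, DNA was not measured, and no explanation was tested.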
